A study of Homo sapiens with 6 samples.

How the data were processed

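RNA was extracted from Raji cells with a silica column kit, and libraries were made from polyadenylated RNA, per the labels' protocols. Cells were grown in medium with 10% serum. The deposited values are FPKM, fragments scaled by gene length and library size, for 58735 genes in 6 libraries, with gene lengths in bases. The submitters' processing notes name CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build hg38, without saying which step each served. The annotation release, the strand setting and any filter are not given in the sources used here. Without a known strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. All 58735 gene coordinates equal those of GENCODE release 29.

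Each deposited FPKM value times its gene length was a whole multiple of 1 step per library, within 0.001 reads for 100% of values, which gave the reads per gene and the depth of each library. With lengths in kilobases the products summed to between 975778 and 1023000 per library, so the divisor the authors used was not the sum over the listed genes. The depth of 19405370 to 24468270 reads puts 3 reads, the limit that a count of 0 allows, at 0.123 to 0.155 CPM. Such limits cover counting error only.

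Libraries were grouped by the treatment label, DMSO or bryostatin, with 3 libraries each. As fixed before the data were examined, genes with a mean of at least 1 FPKM over the 6 libraries (11071 genes) were compared as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, by the moderated test with an intensity trend. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and a 2-fold limit was counted separately. FPKM is not a count, so no count model was used. An exact permutation test of 3 against 3 cannot give a two-sided p under 0.1. The change of the median gene between scalings stayed under 0.1 on the log2 scale, from 0.02 as deposited to -0.03 with TPM. No pair of libraries differed by sampling noise alone, the chi-square of their reads being at least 13.6 per gene.

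The 32 gene lists cover protein kinase C signalling, B-cell identity, antigen presentation, cell death, growth, metabolism, technical controls and other cell types. They hold 719 symbols, 695 of them in the table. Lists with at least 3 tested members were compared with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, a rotation test of whether a list's genes move one way on balance. Where a symbol stood on several rows, the row with the highest mean was used.

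Genes were named by a rule fixed before the data were examined. It takes the 8 protein-coding genes with the largest rise and the 8 with the largest fall among those with an adjusted p under 0.05 and no overlap between groups, 12 genes of interest whether or not they pass, and for each list up to 4 members with an adjusted p under 0.05 or, failing that, the 2 most abundant. Since no gene passed, the first part was repeated at an unadjusted p under 0.05, and the 3 members of each called list with the smallest p were added. Both additions were chosen after the values were seen. Some genes that the rule takes are not reported here.

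Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, 0.1 and 5 FPKM), TPM, median-of-ratios and quantile scaling, moderation without trend or robust, voom precision weights on the recovered reads, the replicate number as a block, protein-coding genes only and each library left out. Removal of trends on gene length and on GC content of the longest GENCODE transcript, by loess with a span of 0.5, and library weights were added after the data were seen.

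The fit was tested on simulated data, with reads drawn for the 11071 genes of the comparison of bryostatin with DMSO in 5 simulations and 200 genes changed in each. Of genes changed 2-fold 90.6% were recovered and of genes changed 4-fold 97.6%, while 4.80% of unchanged genes had an unadjusted p under 0.05. The simulated genes varied independently, without differences shared by many genes of a library. Of 54257 unchanged genes 62 were called. A list shifted 1.5-fold was called in 5 of 5 simulations, and 2 other lists were called in total.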

Results

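Raji is a human B-cell line established from a Burkitt lymphoma, and the cells used here carried a GFP and firefly luciferase reporter according to their labels. They were kept overnight at 37 °C with 1 nM bryostatin-1, a macrocyclic lactone that binds the C1 domains of protein kinase C, or with the solvent DMSO. Polyadenylated RNA was sequenced from 3 libraries per treatment, 6 in all. The number of reads on genes, recovered from the deposited FPKM values, was 24468270, 21379437 and 19883563 in DMSO replicates 1 to 3 and 19405370, 19671580 and 21406275 in bryostatin replicates 1 to 3. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Means are given as FPKM ± SD with n = 3 libraries per group, and fold changes are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes.

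The question was which transcripts differed between bryostatin-treated and solvent-treated cells. No gene of the 11071 tested passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.121. Levels leaned towards higher transcripts of proliferation genes and lower transcripts of NF-kB target, costimulation and MHC class II presentation genes with bryostatin. For cell-cycle genes and the 3 lower lists, the mean of DMSO replicate 3 lay inside the bryostatin range. There the leaning set DMSO replicates 1 and 2 apart from all other libraries. These leanings rest on list tests at a preset correlation, none of which held with an estimated correlation (adjusted p = 0.588 or more). At an unadjusted p under 0.05, limma gave 1954 genes, 1159 higher and 795 lower with bryostatin, where 554 would be expected by chance. Voom precision weights gave 2181 such genes and again 0 after adjustment. Scaling to TPM turned that split to 848 higher and 1099 lower, and quantile normalisation to 893 higher and 1017 lower. The 95% interval of the change lay within 2-fold either way for 10300 genes, 93.0% of those tested. Without DMSO replicate 3, 266 genes passed, 196 higher and 70 lower, but that fit compares only DMSO replicates 1 and 2 with bryostatin. Without any other single library, 0 or 1 gene passed.

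The gene with the smallest p was RNA5SP82, a 5S ribosomal RNA pseudogene of 92 bases on chromosome 1 (247204570 to 247204661, hg38), at 0.493 ± 0.0509 FPKM in DMSO and 4.73 ± 1.43 with bryostatin. It rested on a mean of 4.83 reads per library, and reads of such multicopy sequences cannot be assigned with certainty. Among protein-coding genes with an unadjusted p under 0.05 and no overlap between the groups, the 8 largest differences in each direction were taken after the values were seen, since none passed. CCL22, a chemokine that attracts CCR4-bearing T cells, was at 33.6 ± 10.8 FPKM in DMSO and 15.1 ± 3.84 with bryostatin, 2.12-fold lower (adjusted p = 0.216 in limma). It is gene ENSG00000102962, on chromosome 16 from 57358772 to 57366190. TSC22D3, the glucocorticoid-induced leucine zipper, was 2.01-fold lower, and the chemokine receptors ACKR3 and CCR7 were 1.95-fold and 1.93-fold lower. NCF1, BMF, FCRL3 and SSTR2 had log2 changes of -0.87, -0.85, -0.83 and -0.82. NCF1 has near-identical pseudogenes, so its reads are uncertain. Higher with bryostatin were HIST2H2AC (2.14-fold), HIST1H3I (1.96-fold), LSM6 and PFDN6 (both 1.89-fold), ZWINT (1.83-fold), DTYMK and MRPL51 (both 1.82-fold) and ORC6 (1.81-fold). PFDN6, a prefoldin subunit, was at 11 ± 2.22 FPKM in DMSO and 21.5 ± 2.26 with bryostatin. Across all genes 1430 were higher and 1180 lower in each bryostatin library than in any DMSO library, 23.6% together, where chance gives 10% on average. Differences shared by many genes of a library can lift that share for any split of the libraries. The share was not computed for other splits, so it does not show an effect of treatment.

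Of 32 gene lists fixed before the data were examined, 28 had at least 3 tested members, and camera with a preset correlation of 0.01 called 12 of them, 3 higher and 9 lower with bryostatin. None was called with an estimated correlation (smallest adjusted p = 0.588) or by fry (smallest adjusted p = 0.244). The trafficking list had an estimated correlation of 0.024, near the preset 0.01, and lost its call too. For that list, loss of the call therefore does not show that correlation between genes made it. In the other called lists the estimate ran from 0.0998 for chemokines and cytokines to 0.859 for cell-cycle genes, with 0.628 for MYC targets. There the preset lay well below the estimate, so p-values at the preset can be too small. Whether correlation alone cost those lists their calls was not tested. No member of any list passed in the fit over all genes, so members are named with values. For each called list the 3 members with the smallest p were added after the values were seen.

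Cell-cycle genes were called higher by camera (adjusted p = 1.13e-09; adjusted p = 0.588 with an estimated correlation), with a mean log2 change of 0.55. All 34 tested members were higher with bryostatin, 18 of them at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. AURKB, a mitotic kinase, was at 28.2 ± 8.71 FPKM in DMSO and 48.3 ± 4.41 with bryostatin. BIRC5, which encodes survivin, was at 24.3 ± 7.93 and 41.3 ± 5.44, and E2F1, a transcription factor of the G1/S transition, at 40.2 ± 8.97 and 60.0 ± 6.64. The DNA replication genes PCNA and MCM7 were the most abundant members, at 126.3 ± 54.2 and 77.9 ± 25.1 FPKM in DMSO and 181.4 ± 23.3 and 132.7 ± 26.9 with bryostatin. DMSO replicate 3 did not follow its group: the list mean, relative to the mean of the 6 libraries, was -0.63 and -0.44 in DMSO replicates 1 and 2 but 0.24 in DMSO replicate 3, against 0.44, 0.18 and 0.22 with bryostatin. Without that library the mean log2 change was 0.81.

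MYC target genes, mostly of ribosome assembly, were called higher as well (adjusted p = 2.44e-07; adjusted p = 0.588 with an estimated correlation), with all 32 members higher, 12 at an unadjusted p under 0.05 and 5 passing when adjusted over the list alone. HSPE1, a mitochondrial chaperonin subunit, was at 21.3 ± 3.0 FPKM in DMSO and 39.7 ± 8.29 with bryostatin, and the nucleolar genes RRP9 and NOP16 had log2 changes of 0.49 and 0.46. The abundant NPM1 and ODC1 had log2 changes of 0.11 and 0.21, with overlapping libraries. Replication-dependent histone genes were called higher (adjusted p = 0.0370; adjusted p = 0.694 with an estimated correlation), 13 of 14 tested members being higher, 3 of them at an unadjusted p under 0.05 and 1 passing over the list alone. HIST1H1C, HIST2H2AC and HIST1H1B had log2 changes of 0.75, 1.10 and 0.74, and the most abundant member, HIST1H2BK, 0.11. Most mRNAs of this class lack a poly(A) tail, so poly(A)-enriched libraries count only part of them. The call was lost with the length trend removed and with a filter of 5 FPKM (adjusted p = 0.110 and 0.0825), where the mean log2 change was 0.27 and 0.65, against 0.34 in the comparison itself. It was also lost without DMSO replicate 1 or bryostatin replicate 2, with means of 0.31 and 0.31, and without DMSO replicate 2, where the mean was 0.16.

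**Figure D1:**
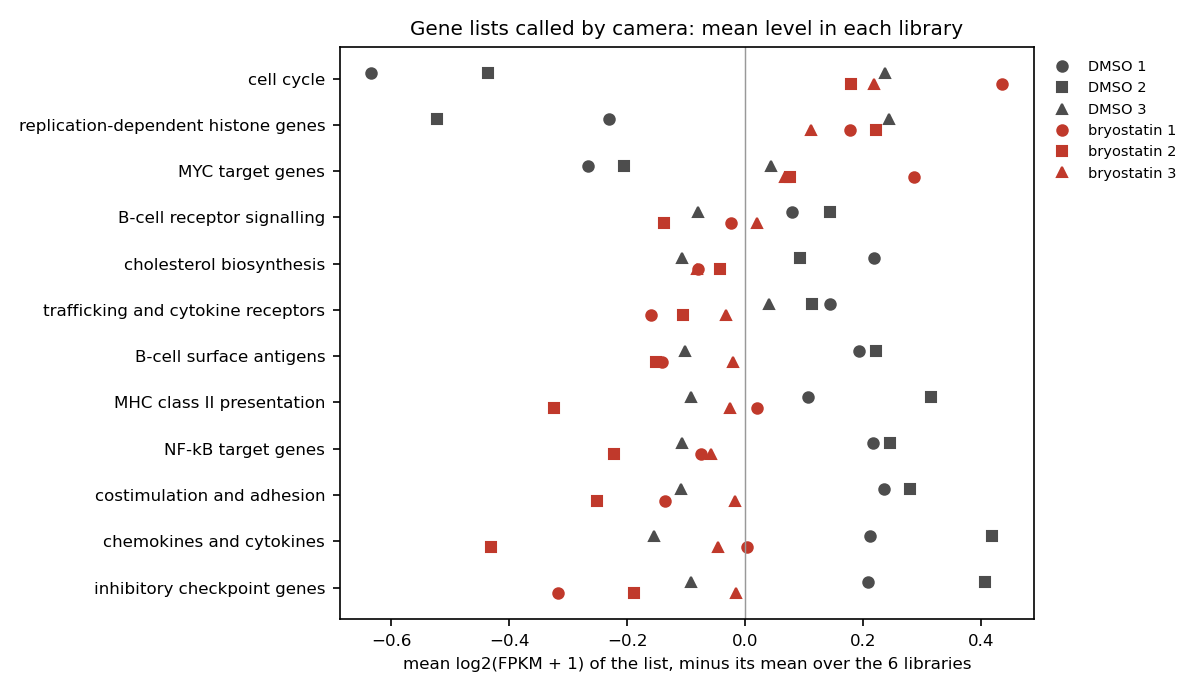
Mean log2(FPKM + 1) of the members of each of the 12 called lists in each library, minus the mean over the 6 libraries (x axis, log2 units); grey symbols are DMSO libraries, red symbols bryostatin libraries and the shape gives the replicate. For cell-cycle genes DMSO replicates 1 and 2 lie at -0.63 and -0.44, while DMSO replicate 3 lies at 0.24, inside the bryostatin range of 0.18 to 0.44.

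NF-kB target genes were called lower (adjusted p = 2.70e-04; adjusted p = 0.588 with an estimated correlation), with a mean log2 change of -0.24. Of 32 tested members 24 were lower, 10 of them at an unadjusted p under 0.05, and 3 members were higher at that level. When adjusted over the list alone, 3 members passed. TNFAIP3, a deubiquitinase that restrains NF-kB signalling, was at 23.9 ± 0.675 FPKM in DMSO and 16.0 ± 2.60 with bryostatin, and the antiapoptotic BCL2A1 was at 25.5 ± 5.02 and 14.7 ± 2.25. The abundant LTB and PLEK had log2 changes of -0.27 and -0.24 with overlapping libraries, and the sign of LTB turned without DMSO replicate 2 (0.07). Chemokines and cytokines, 9 of whose listed genes other lists also hold, were called lower with 12 of 13 members lower (adjusted p = 0.00545; adjusted p = 0.588 with an estimated correlation) and 1 passing over the list alone. Besides CCL22 they included EBI3, a cytokine subunit, at 132.8 ± 36.1 FPKM in DMSO and 86.5 ± 12.3 with bryostatin, and CXCL10 at 2.29 ± 0.596 and 1.36 ± 0.587. This call was lost without a filter on low values (adjusted p = 0.170), with a filter of 0.1 FPKM (adjusted p = 0.0579) and without DMSO replicate 2 or bryostatin replicate 2.

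Costimulation and adhesion genes were called lower, 16 of 19 members being lower and 6 at an unadjusted p under 0.05 (adjusted p = 3.20e-04; adjusted p = 0.588 with an estimated correlation). CD80, a CD28 ligand, was at 11.4 ± 1.81 FPKM in DMSO and 7.46 ± 0.686 with bryostatin. CD84, an adhesion receptor of the SLAM family, was at 11.3 ± 2.86 and 6.58 ± 1.52. CD48 had a log2 change of -0.45 and CD70, the most abundant member, -0.16. Inhibitory checkpoint genes had only 5 tested members, all lower (adjusted p = 0.0105; adjusted p = 0.588 with an estimated correlation). CD47, the ligand of SIRPA, was at 12.8 ± 1.06 FPKM in DMSO and 10.7 ± 0.839 with bryostatin, and HAVCR2, TNFRSF14 and FCRLB had log2 changes of -0.40, -0.40 and -0.41. The checkpoint call was lost without DMSO replicate 2 (adjusted p = 0.0938), where TNFRSF14 had -0.13 and HAVCR2 -0.26. FCRLB had -0.23 without bryostatin replicate 1.

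B-cell surface antigens, 8 of whose listed genes are in other lists, were called lower with 18 of 23 members lower (adjusted p = 0.00633; adjusted p = 0.588 with an estimated correlation). FCRL3, an Fc receptor-like protein, was at 8.90 ± 1.49 FPKM in DMSO and 4.75 ± 2.03 with bryostatin, the TNF receptor family member CD27 at 91.5 ± 13.7 and 64.6 ± 10.0, and the tetraspanin CD37 at 97.9 ± 10.1 and 74.9 ± 9.72. CD74, the invariant chain of MHC class II, was at 2058 ± 93.8 and 1667 ± 175.3. B-cell receptor signalling genes were called lower with 16 of 25 members lower (adjusted p = 0.00867; adjusted p = 0.588 with an estimated correlation) and a mean log2 change of -0.09. The phosphatase INPP5D, the exchange factor VAV2 and the kinase LYN had log2 changes of -0.32, -0.32 and -0.31, and the receptor chains CD79A and CD79B, its most abundant members, 0.14 and -0.10. MHC class II presentation genes were called lower with 17 of 19 members lower (adjusted p = 0.00154; adjusted p = 0.588 with an estimated correlation). The lysosomal proteases LGMN and CTSS had log2 changes of -0.54 and -0.35, HLA-DRB5 -0.64 and HLA-DRA -0.20. Reads of HLA genes can fall on several near-identical copies, so single HLA values are uncertain. Without DMSO replicate 2 the calls of all 3 of these lists were lost (adjusted p = 0.107, 0.0992 and 0.0992), with mean log2 changes of -0.15, -0.046 and -0.12. That of B-cell receptor signalling was also lost without bryostatin replicate 2, with a mean of -0.049.

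Trafficking and cytokine receptor genes were called lower with 15 of 18 members lower (adjusted p = 0.00406; adjusted p = 0.588 with an estimated correlation). CXCR5, which guides B cells into follicles, was at 3.91 ± 0.586 FPKM in DMSO and 2.50 ± 0.244 with bryostatin. The oxysterol receptor GPR183 was at 3.53 ± 0.755 and 2.02 ± 0.291, and CCR7 at 15.6 ± 4.14 and 7.76 ± 3.06. The abundant P2RY8 and S1PR2 had log2 changes of -0.19 and 0.02, the latter of either sign depending on the scaling. Cholesterol biosynthesis genes were called lower with 16 of 23 members lower (adjusted p = 0.00249; adjusted p = 0.607 with an estimated correlation). ACAT2, SC5D, HMGCS1 and INSIG1 had log2 changes of -0.30, -0.34, -0.34 and -0.16, whereas PMVK, the phosphomevalonate kinase, was at 36.0 ± 7.69 FPKM in DMSO and 63.5 ± 11.3 with bryostatin. Over the 12 called lists, DMSO replicate 3 lay nearer to the bryostatin mean than to the mean of the other DMSO libraries in 11. For histone and cholesterol genes its list means of 0.24 and -0.11 lay beyond all bryostatin libraries, on the side away from the other DMSO libraries.

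Among the genes fixed in advance, the B-cell antigens CD20 (MS4A1) and CD22 overlapped between the groups. MS4A1 was at 221.6 ± 57.7 FPKM in DMSO and 240.5 ± 78.1 with bryostatin, and CD22 at 157.4 ± 62.0 and 154.2 ± 47.3 (adjusted p = 0.894 and 0.990 in limma). The log2 change of CD22 was -0.01 with a 95% interval from -0.78 to 0.76, so a change of 1.5-fold either way was not excluded. CD79A (0.14), CD58 (-0.0025) and BCL6 (-0.05) also overlapped, as did MYC at 117.3 ± 18.8 and 103.2 ± 5.91 FPKM. FAS, a death receptor, lay lower in each bryostatin library than in any DMSO library, at 14.2 ± 0.576 FPKM in DMSO and 10.8 ± 0.407 with bryostatin (1.29-fold, adjusted p = 0.216 in limma). FAS is gene ENSG00000026103, on chromosome 10 from 88990582 to 89015785. ICAM1, an adhesion ligand of LFA-1 (ENSG00000090339, chromosome 19, 10270835 to 10286615), was at 38.8 ± 5.95 and 28.6 ± 1.91 FPKM (adjusted p = 0.221). PRKCB, the protein kinase C beta isoform (ENSG00000166501, chromosome 16, 23835946 to 24220611), was at 24.4 ± 3.61 and 17.0 ± 2.15 FPKM, 1.41-fold lower (adjusted p = 0.217). PRKCD, the delta isoform, was at 53.9 ± 3.33 and 52.0 ± 0.857 FPKM, and the list of protein kinase C and other C1-domain genes, 7 of 11 lower, was not called (adjusted p = 0.251). PRDM1 had a mean of 70.0 reads per library and lay below the level needed for testing, at 0.694 FPKM in DMSO and 0.310 with bryostatin.

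**Figure D2:**
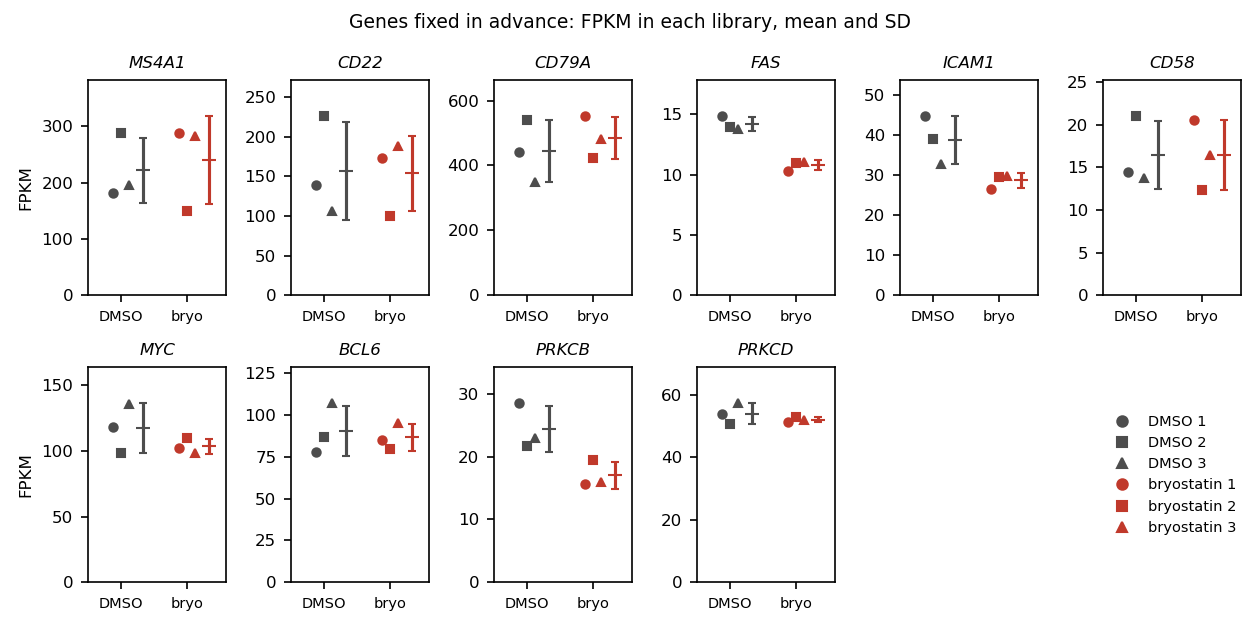
FPKM (y axis, from 0) of 10 genes fixed in advance, in each DMSO (grey) and bryostatin (red) library; shapes give the replicate, and the bar beside the symbols gives mean and SD of the 3 libraries. Mean FAS is 14.2 FPKM in DMSO and 10.8 with bryostatin, without overlap, while the libraries of MS4A1 and CD22 overlap.

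Lists not called included immediate early and MAPK feedback genes, 13 of 17 higher (adjusted p = 0.268). Their mean log2 change was 0.22 and their median 0.17, and 1 member, a higher one, had an unadjusted p under 0.05. Their list mean per library was -0.14, 0.26 and -0.45 in DMSO and 0.31, -0.37 and 0.39 with bryostatin, and the call appeared without DMSO replicate 2 (adjusted p = 0.0304) or bryostatin replicate 2 (adjusted p = 0.00348), against adjusted p = 0.774 with an estimated correlation over all libraries. DUSP2 and JUND, the most abundant members, had log2 changes of -0.07 and 0.03, with the sign of JUND depending on the scaling. The germinal centre list (adjusted p = 0.405) held TCF3 with 0.16 and SERPINA9 with -0.73. The plasma-cell list (adjusted p = 0.854) held MZB1, an endoplasmic reticulum chaperone of antibody assembly, at 81.2 ± 4.09 FPKM in DMSO and 110.2 ± 6.82 with bryostatin, and JCHAIN with -0.18. In the MHC class I list (adjusted p = 0.248) CALR had 0.36 and HLA-B -0.37, and the call appeared with quantile normalisation (adjusted p = 0.0396) and without bryostatin replicate 1 (adjusted p = 0.0484), against adjusted p = 0.694 with an estimated correlation over all libraries. For NK-cell receptor ligands (adjusted p = 0.577) HLA-E had 0.02, of either sign depending on the scaling. The death receptor pathway (adjusted p = 0.755) included FAS, given above, and the BCL2 family and granzyme inhibitor list (adjusted p = 0.504) MCL1 with -0.13 and BIRC3 with -0.18. In the BCL2 family list 4 members were lower and 2 higher at an unadjusted p under 0.05, and 3 passed over the list alone, all lower. CDK inhibitors and p53 targets (adjusted p = 0.559) held BTG2 with -0.31 and RRM2B with -0.03. There 4 members were higher and 1 lower at an unadjusted p under 0.05, and 2 higher and 1 lower passed over the list alone. Passing over their list alone were also 1 higher plasma-cell member and 1 lower member each of the MHC class I and death receptor lists.

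Interferon-stimulated genes were not called (adjusted p = 0.236), with BST2 and ISG15 at log2 changes of -0.01 and 0.11, nor were genes of the unfolded protein response (adjusted p = 0.385), where HSPA5 had 0.24. Glycolysis genes (adjusted p = 0.854) included GAPDH with -0.21 and ENO1 with 0.10. Cytosolic ribosomal protein genes (adjusted p = 0.755) had a mean log2 change of 0.02 but a median of -0.01 and a test direction towards lower, with RPS18 at 0.21 and RPS2 at -0.04, and the sign of their mean turned with TPM, median-of-ratios or quantile scaling. Housekeeping genes (adjusted p = 0.236) included ACTB with -0.06, whose sign turned with quantile normalisation. Their call appeared without a filter on low values (adjusted p = 0.0290; adjusted p = 0.694 with an estimated correlation and the filter). Mitochondrially encoded mRNAs (adjusted p = 0.190) had a mean log2 change of 0.18 and a median of 0.14, with 10 of 13 members higher. The most abundant, MT-CO1 and MT-CO2, had -0.05 and 0.03, both of either sign depending on the scaling. The call of this list appeared with quantile normalisation (adjusted p = 0.0396) and without bryostatin replicate 3 (adjusted p = 0.0185). With an estimated correlation over all libraries its adjusted p was 0.774.

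Most markers of other cell types lay under 0.1 FPKM or were not tested. Of 14 T-cell markers 3 were tested, with LCK at 44.9 ± 4.84 FPKM in DMSO and 39.4 ± 2.36 with bryostatin and TRBC2 at 23.0 ± 13.1 and 17.1 ± 6.73. The other tested marker, TRAC, added after the values were seen, was at 6.09 ± 4.69 and 9.49 ± 5.46 FPKM, a log2 change of 0.57 with overlapping libraries. The list was not called (adjusted p = 0.577), and its mean of 0.02 and median of -0.18 differed in sign. Among NK-cell markers NKG7 was highest, at 3.12 ± 1.32 and 2.62 ± 0.705 FPKM, followed by PRF1 at 0.289 ± 0.191 and 0.323 ± 0.0680. The highest myeloid markers were ITGAX at 0.785 ± 0.467 and 0.594 ± 0.182 FPKM and S100A9 at 0.664 ± 0.210 and 0.268 ± 0.238. Of erythroid markers ALAS2 reached 0.0723 ± 0.0394 and 0.0466 ± 0.00300 FPKM, and of epithelial and fibroblast markers COL1A1 reached 0.606 ± 0.172 and 0.402 ± 0.118. HBA2 and KRT19 had at most 3 reads in a library.

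The libraries resembled each other closely, with a mean Pearson correlation across genes of 0.980 for the 6 pairs within a group and 0.974 for the 9 pairs between groups. The lowest correlation within a group was 0.971 and the highest between groups 0.981, both in pairs with DMSO replicate 3, so the 2 kinds of pair overlapped. The gap between the 2 means was 0.00605, and over the alternatives it ranged from 0.000957 without bryostatin replicate 1 to 0.0107 without DMSO replicate 3. The first principal component, with 41.4% of the variance, ran from -24.3 in DMSO replicate 1 to 24.2 in bryostatin replicate 1, with DMSO replicate 3 at -4.24 and bryostatin replicate 2 at 4.09. Short genes lay higher and long genes lower with bryostatin. Across 9265 protein-coding genes, which are not independent replicates, the Spearman correlation of log2 change with gene length was -0.31. The median log2 change was 0.13 in the shortest sixth and -0.08 in the longest. The slope on log2 length was 0.04, 0.02 and 0.05 in the DMSO libraries and -0.06, -0.03 and -0.02 in the bryostatin libraries. Each slope was taken on a library's deviations from each gene's mean over the 6 libraries, so its sign is relative.

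**Figure D3:**
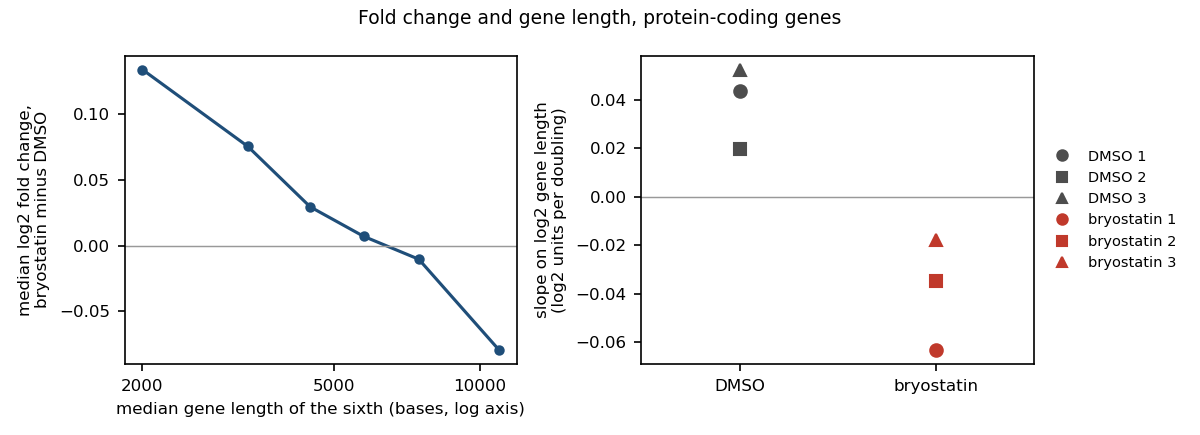
Left, median log2 fold change (y axis) of protein-coding genes in 6 classes of gene length (x axis, bases, log axis), from 0.13 in the shortest to -0.08 in the longest class. Right, the slope on log2 gene length (log2 units per doubling) of each library's log2 values minus each gene's mean over the 6 libraries. DMSO libraries are grey, bryostatin libraries red, and shapes give replicates. Slopes are relative to that mean, so only differences between libraries count, and the DMSO slopes lay above the bryostatin slopes.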

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

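The removal of trends on gene length and GC content and the library weights were chosen after the data were seen, and the other alternatives before. The cause of the differences below was not tested, except that each fit without a library has fewer samples. All 12 called lists kept their direction in every alternative, with mean log2 changes of 0.38 to 0.81 for cell-cycle genes, 0.20 to 0.38 for MYC targets, 0.16 to 0.65 for histones and -0.35 to -0.17 for NF-kB targets. They were -0.31 to -0.15 for B-cell surface antigens, -0.16 to -0.046 for B-cell receptor signalling, -0.32 to -0.11 for MHC class II, -0.39 to -0.20 for costimulation and adhesion, -0.48 to -0.16 for checkpoint genes, -0.47 to -0.15 for chemokines and cytokines, -0.27 to -0.15 for trafficking and -0.23 to -0.061 for cholesterol biosynthesis. With an estimated correlation and with fry, 0 lists were called, against 12. Leaving out 1 library gave 7 lists (without DMSO replicate 2) to 13 lists (without bryostatin replicate 1). The count of genes that passed was 0, 1 with a pseudocount of 0.1 and 1 with TPM, which was RNA5SP82 in both cases, at least 2-fold in each. Leaving out 1 library gave 0 (without DMSO replicate 1, for example) to 266 genes (without DMSO replicate 3), and 0 to 25 genes of at least 2-fold. The number at an unadjusted p under 0.05 was 917 without bryostatin replicate 1, 2868 without DMSO replicate 3 and 3213 with library weights, which gave DMSO replicate 3 a weight of 0.370. With the replicate number as a block it was 1191, 0 genes passed and 12 lists were called. Residuals of libraries sharing a number had correlations of -0.29, -0.32 and -0.11, while DMSO replicate 1 and bryostatin replicate 2 had 0.32. The residuals of a group cancel for each gene, which ties these values together. They showed no pairing by number but do not settle it. The gap between mean correlations within and between groups was 0.00605, and 0.00225, 0.00324 and 0.00943 with no filter and filters of 0.1 and 5 FPKM. The depth of 19405370 to 24468270 reads limits mainly short and weakly expressed genes such as RNA5SP82, with 4.83 reads per library.

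None of the lists whose mean log2 change turned sign was called in the comparison of all libraries. Of the genes that turned, LTB and TRBC2 had the largest values there, -0.27 and -0.33. The death receptor list had -0.0011 without a filter, -0.039 with TPM, -0.0065 with median-of-ratios scaling, -0.0052 with quantile normalisation, -0.015 with voom, -0.017 with the length trend removed, -0.021 with length and GC trends removed and -0.0068 with library weights. Cytosolic ribosomal proteins had -0.029 with TPM, -0.0023 with median-of-ratios scaling, -0.028 with quantile normalisation, -0.026 with the length trend removed, -0.028 with length and GC trends removed and -0.048 with library weights. T-cell markers had -0.0016 without a filter, -0.011 with TPM, -0.00032 with median-of-ratios scaling, -0.053 with quantile normalisation, -0.044 with the length trend removed and -0.045 with length and GC trends removed. The plasma-cell list had 0.038 with a filter of 5 FPKM, and CDK inhibitors and p53 targets had -0.0018 with TPM.

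Among genes, JUND had -0.022 with TPM, -0.094 with quantile normalisation, -0.057 with the length trend removed, -0.093 with length and GC trends removed and -0.028 with library weights. HLA-E had -0.030 with TPM, -0.0038 with median-of-ratios scaling, -0.072 with quantile normalisation, -0.044 with the length trend removed, -0.046 with length and GC trends removed and -0.014 with library weights. S1PR2 had -0.030 with TPM, -0.0040 with median-of-ratios scaling, -0.094 with quantile normalisation, -0.031 with the length trend removed and -0.034 with length and GC trends removed. MT-CO2 had -0.018 with TPM, -0.034 with the length trend removed and -0.032 with length and GC trends removed. With quantile normalisation MS4A1 had -0.017, ACTB 0.0092 and MT-CO1 0.055. With library weights CD22 had 0.015, CD58 0.010, BCL6 0.080, ACTB 0.025 and MT-CO1 0.015.

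When single libraries were left out, the lowest and highest log2 changes of lists that turned sign were -0.043 to 0.031 for the plasma-cell list, -0.11 to 0.043 for NK-cell receptor ligands, -0.049 to 0.066 for the death receptor list, -0.067 to 0.024 for glycolysis, -0.044 to 0.081 for cytosolic ribosomal proteins and -0.25 to 0.33 for T-cell markers. For genes they were -0.071 to 0.39 for MS4A1, -0.25 to 0.29 for CD22, -0.017 to 0.30 for CD79A, -0.17 to 0.18 for CD58, -0.16 to 0.071 for BCL6, -0.42 to 0.17 for DUSP2, -0.038 to 0.13 for JUND and -0.69 to 0.071 for LTB. They were -0.27 to 0.30 for HLA-E, -0.24 to 0.15 for RRM2B, -0.064 to 0.047 for BST2, -0.074 to 0.13 for S1PR2, -0.16 to 0.073 for RPS2, -0.19 to 0.12 for ACTB, -0.13 to 0.031 for MT-CO1, -0.091 to 0.12 for MT-CO2 and -0.75 to 0.080 for TRBC2. Printed genes that kept their sign but moved by over 1.5 times were PRKCD (-0.091 to -0.0035), CD79B (-0.29 to -0.0059), HIST1H2BK (0.012 to 0.26), MCL1 (-0.28 to -0.035), ODC1 (0.065 to 0.39), TNFRSF14 (-0.65 to -0.13), PLEK (-0.42 to -0.083), MYC (-0.29 to -0.062), BIRC3 (-0.30 to -0.074), HLA-DRA (-0.32 to -0.080), RPS18 (0.086 to 0.28), TCF3 (0.075 to 0.26), CD70 (-0.28 to -0.081), NPM1 (0.058 to 0.21), BTG2 (-0.45 to -0.16), PCNA (0.33 to 0.92), FCRLB (-0.53 to -0.23), HMGCS1 (-0.46 to -0.19), HSPA5 (0.14 to 0.30), JCHAIN (-0.24 to -0.11), ISG15 (0.069 to 0.19), HLA-DRB5 (-0.83 to -0.38), ENO1 (0.059 to 0.16), INSIG1 (-0.21 to -0.10), LCK (-0.27 to -0.12) and HAVCR2 (-0.52 to -0.26).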

Other observations

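The tests on splits, on the treatment and on growth state and the positions of the other libraries were chosen only after the results were seen, and DMSO replicate 3's list values were known before the test for a mislabelled library was thought of. In the fit without that library, genes named after the values were seen included the mitotic genes CDC20 and CCNB1, with log2 changes of 1.07 and 1.11 (limma adjusted p = 0.0338 and 0.0447), CCNA2 with 0.90 and the transcription factor FOXM1 with 0.85 (both adjusted p = 0.0338). Lower there were SPN, the sialophorin CD43, with -1.06 and the activation marker CD83 with -0.78 (both adjusted p = 0.0338), and BCL2A1, EBI3 and SERPINA9 with -0.90, -0.83 and -0.95 (limma adjusted p = 0.0448, 0.0456 and 0.0464).

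The 6 libraries can be split into 3 and 3 in 10 ways, too few for a test, so chance was neither excluded nor shown as the source of these counts. At an unadjusted p under 0.05 the treatment split gave 1954 genes and the highest other split 1188, so no other split gave as many. For called lists, 3 of 10 splits, the treatment split with its 12 lists among them, gave at least as many, with a highest other value of 15. Looked at after the counts were seen, DMSO replicates 1 and 2 with bryostatin replicate 1, 2 or 3 gave 14, 9 and 15 lists. Splits that parted DMSO replicate 1 from DMSO replicate 2 gave 0 to 5. The list calls thus went with DMSO replicates 1 and 2 being kept together, whichever library joined them. For genes that passed, and for the 2-fold limit, the treatment count was 0, so that all 10 splits had to give at least as many and nothing about chance follows (highest other values 52 and 27). The split of DMSO replicates 1 and 3 and bryostatin replicate 2 from the other libraries gave the 52 genes. It was picked after the counts were seen and could reflect a structure of the samples other than treatment, which was not tested. Among lists looked at after the split was seen, immediate early genes lay at -0.14, -0.45 and -0.37 in those 3 libraries and at 0.26, 0.31 and 0.39 in DMSO replicate 2 and bryostatin replicates 1 and 3. The 3 tested T-cell markers lay at -0.09, -0.55 and -0.56 and at 0.61, 0.16 and 0.42.

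Short genes were higher and long genes lower with bryostatin. A bias of the libraries by length could account for it. Within 305 C2H2 zinc-finger genes the slope was -0.050 (95% bootstrap interval over genes -0.078 to -0.022), against -0.077 over all protein-coding genes. These genes share a DNA-binding domain, not 1 function, so their slope does not separate such a bias from regulation. GC content did not account for the length trend, since the slope on length with GC content in the regression was 1.02 times that without (1.01 to 1.04, bootstrap over 9261 genes). An effect of the treatment was not separated from such a bias, with a two-sided exact permutation p of 0.1 for the 6 slopes, the smallest that 3 against 3 can give.

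Cell-cycle and MYC target genes were higher with bryostatin on average, but the cell-cycle mean of DMSO replicate 3 lay inside the bryostatin range, while its MYC target mean of 0.04 lay just below the lowest bryostatin value of 0.07. The length trend did not account for it, since 0.929 of the cell-cycle change stayed with the trend removed (0.912 to 0.947, bootstrap over genes), and 0.875 of the MYC target change. Over the 266 genes that passed without DMSO replicate 3, that library lay at a median position of 0.824, with 0 at the other DMSO libraries and 1 at bryostatin. The bootstrap interval of 0.756 to 0.878 resampled genes, which are not independent replicates, and does not measure the spread between libraries. The other 5 libraries, each placed on the 266 genes of smallest p in a fit without it, lay at -0.23 to 0.47. At most 1 of those genes passed in each of these fits, against all 266 without DMSO replicate 3, so the reference is not a like one. Genes picked for a gap between the remaining libraries overstate that gap, which moves a left-out library away from 0 even without a group effect. Among the 266 genes the median position of DMSO replicate 3 was 0.874 for the 196 higher with bryostatin and 0.731 for the 70 lower. It was 0.978 for the 20 on the cell-cycle or MYC target lists, nearly all of them cell-cycle genes, so this value says little about MYC targets. A mislabelled library or the growth state of single cultures could account for these positions, which do not tell them apart. The cell-cycle mean of DMSO replicate 3, 0.24, lay inside the bryostatin range of 0.18 to 0.44. Its slope on length, 0.052, however, was the highest of all 6 libraries, against a bryostatin range of -0.063 to -0.018. An effect of treatment was not decided, with an exact permutation p of 0.3 for the 6 cell-cycle means and of 0.1, the smallest possible, for the 6 MYC target means.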
